A study of Mus musculus with 4 samples.

How the data were processed

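B cell receptor libraries were made from skull and from sternum bone marrow of C57BL/6 mice, an inbred laboratory strain. The labels' protocols describe a flow cytometry sort that combined CD19-positive, CD138-negative B cells with CD138- and TACI-positive, IgD-negative antibody-secreting cells, both without CD3e. Single cells were then prepared on the 10x Genomics Chromium system and sequenced on an Illumina NextSeq. There was 1 receptor library per bone. Gene expression libraries of the same sorts are listed in the series and were not analysed here. How many animals each library came from is not given in the sources used here.

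The submitters' processing notes name bcl2fastq, Cell Ranger 9.0.1 and the mouse build mm10, without saying which step each served; the receptor reference was not given in the sources used here. The deposited tables hold one assembled contig per line, with a cell barcode, a chain, segment calls, framework and CDR sequences, a clonotype number, and raw counts of UMIs and reads, per the file headers. A UMI is a molecular identifier that counts captured mRNA molecules. The authors' counts are not normalized. Every contig in both tables was marked as belonging to a cell, high-confidence, full-length and productive, so contigs without these marks were already removed. The cell mark is a call of the submitters' processing. It does not exclude droplets that held only free RNA. Depth differed between the tables. The skull table had 2811423 UMIs at 10.3 reads per UMI and the sternum table had 757357 UMIs at 23.0 reads per UMI.

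The main population was every barcode with exactly 1 productive heavy-chain (IGH) contig, called a cell below. Barcodes with 2 productive IGH contigs, which doublets can give, were left out, and no other doublet caller was run. Light-chain values used cells with exactly 1 productive light chain. A clone was a set of cells of 1 library with the same IGHV gene, IGHJ gene and CDR3 nucleotides, and an expanded clone had 2 or more cells. The cell with the most IGH UMIs represented its clone for isotype and light chain. Isotypes and light chains were counted over cells, and V, D and J segments, CDR3 and mutation over clones. Diversity was the mean of 100 random draws of 2125 cells. High-UMI cells had at least 10 times the median IGH UMIs of the IGHM and IGHD cells of their library, which set the limit at 50 UMIs in the skull and 30 in the sternum. This is a range of a count and not a cell type, and 33 skull and 29 sternum cells lay within a factor of 2 of the limit.

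Mutation was counted as mismatches over framework 1 to framework 3 against the most common sequence of the same V gene among IGHM and IGHD clones of both libraries, for the 81 V genes with at least 5 such clones. A clone took the median of its cells and was called mutated at 2 or more mismatches. For all 81 genes the inferred sequence was identical to a stretch of the V segment in the GENCODE M21 annotation of GRCm38, which is the build mm10. Coordinates come from that annotation. All 92 IGHV genes and all 88 light-chain V genes in the tables were found in it by symbol.

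Genes were named by a rule fixed before the data were examined. It took fixed lists of receptor genes (phosphatidylcholine-binding B-1 genes IGHV11-1, IGHV11-2 and IGHV12-3 with light partners IGKV14-126 and IGKV4-91; IGHV7-1 and IGKV7-33, which encode phosphorylcholine-binding antibodies; IGHV5-2; the families nearest to and farthest from the D segments; IGHV1-72; IGHD4-1 and IGHD1-1; all constant genes; J segments). It added, among V genes with 30 or more clones over both libraries, the 8 IGHV and 5 light V genes with the highest and the same numbers with the lowest ratio of skull to sternum shares, the 5 most used IGHV and 3 most used light V genes, the 5 largest clones per library, and up to 10 shared clones.

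With 1 library per bone there was no replicate, so no test between the bones was possible and no p-value is given. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Differences between animals, sorts or library preparations are not in them. Those over cells treat the cells of 1 clone as independent, so they are too narrow where a few clones hold many of the cells. Intervals of differences between shares are Newcombe intervals from Wilson limits, and that of mean CDR3 length is a normal interval, with the same limits to what they cover. No interval is adjusted for the number of genes or segments compared. For a count of 0 the limit that 3 counts would give is stated. Analyses ran in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. The functions were tested on simulated contig tables with as many clones as the real libraries (2013 and 1809) and 40 V genes. All 20 shared clones, 404 of 404 expanded skull cells and 221 of 221 mutated skull clones were found, and the median ratio of the 10 changed genes was 1.60 against a true value of 1.60 and that of the unchanged genes 0.84 against 0.80. The simulated tables held no free RNA, doublets or sequence errors, and each mutated clone had more mismatches than the limit requires. They thus check the code and not the calls made in low-UMI cells.

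Alternatives fixed in advance were all barcodes with an IGH contig, only cells with 1 IGH and 1 light chain, a minimum of 3 IGH UMIs, cells or clones as the unit, other clone rules (the authors' clonotype numbers, 85% CDR3 identity, heavy and light match, amino-acid match), unswitched clones only for IGHV use, reference V segments, mutation limits of 1 and 4 mismatches, and high-UMI limits of 5 and 20 times the median. A minimum of 10 UMIs for heavy or for light contigs, high-UMI cells only (for expansion and shared clones), and the skull limit in both libraries were added after seeing the data.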

Results

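The series concerns lymphoid structures in skull bone marrow. The receptor libraries allow the B cell repertoire of the skull marrow to be set beside that of the sternum marrow, a site away from the head. The skull table held 6348 contigs from 3614 barcodes and that of the sternum held 6547 contigs from 3927 barcodes. A productive heavy chain was found in 67.5% of skull barcodes (2438 of 3614, interval 65.9 to 69.0%) and 57.0% of sternum barcodes (2240 of 3927, 55.5 to 58.6%). The remaining barcodes, 1176 and 1687, had a light chain only. Among barcodes with a heavy chain, 6.11% in the skull and 5.13% in the sternum had 2 productive IGH contigs and were set aside. This left 2289 skull cells in 2013 clones and 2125 sternum cells in 1809 clones. Heavy-chain contigs had a median of 5 UMIs in the skull and 3 in the sternum. There was 1 library per bone and thus no replicate, and intervals given with a share are exact 95% intervals of counting error.

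Both bones held 2 ranges of cells by IGH UMIs, and the upper range was larger in the skull library. IGHM and IGHD cells, the unswitched isotypes of B cells, had medians of 5 UMIs in the skull and 3 in the sternum. High-UMI cells had medians of 890 and 445.5 UMIs. They made up 15.8% of skull cells (361 of 2289, 14.3 to 17.3%) and 4.80% of sternum cells (102 of 2125, 3.93 to 5.80%). They held 97.7% of the IGH UMIs of all skull cells and 93.6% of those of all sternum cells. No IGHD cell reached the range in either bone (0 of 271, which allows up to 1.11%, and 0 of 597, up to 0.503%). By contrast, 81.8% of skull IGHA cells did so (99 of 121, 73.8 to 88.2%) and 15.7% of sternum IGHA cells (31 of 197, 10.9 to 21.6%). The sort mixed B cells with antibody-secreting cells, which carry large amounts of immunoglobulin mRNA, in a proportion that the labels do not give. The sort can therefore set the high-UMI share. Antibody-secreting cells were sorted as IgD-negative, so the sort can also set the absence of IGHD from the range.

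**Figure D1:**
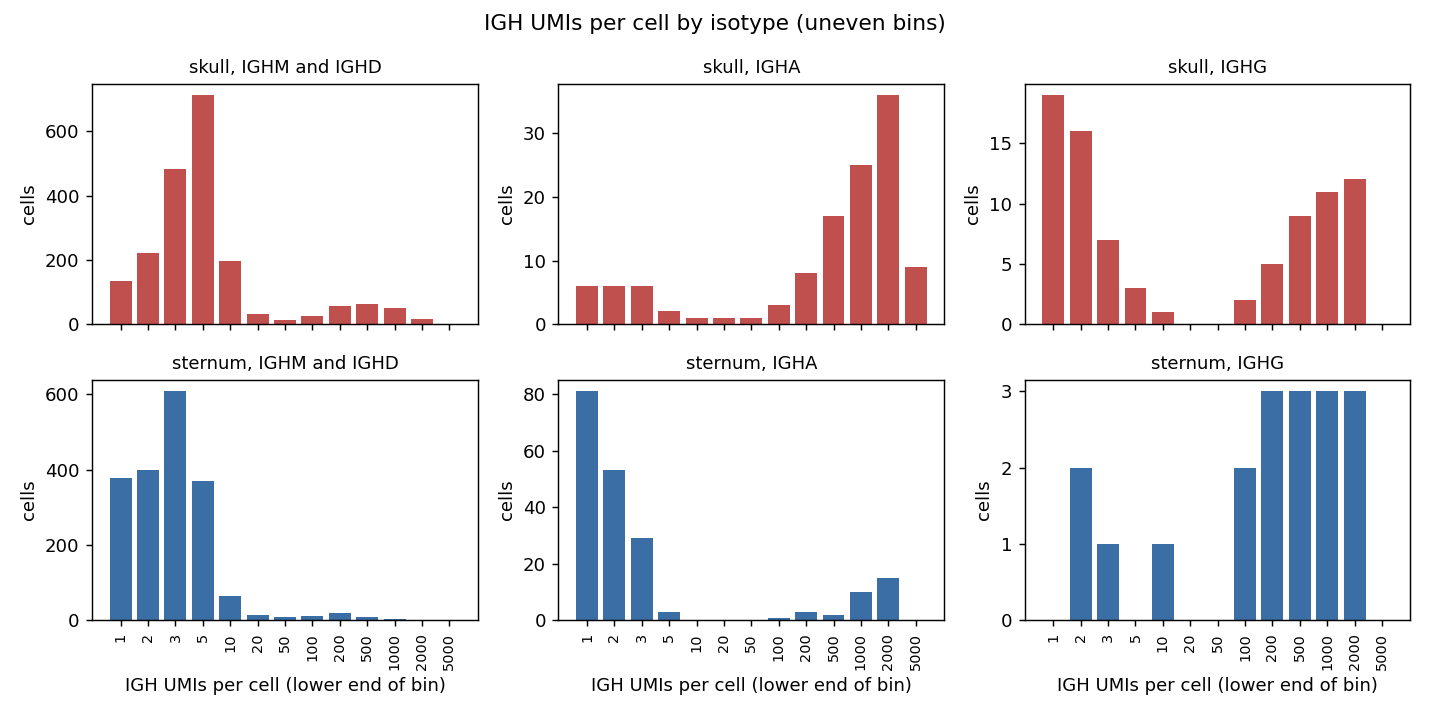
IGH UMIs per cell (x axis, lower end of each uneven bin) against the number of cells (y axis, a separate scale per panel) for IGHM and IGHD, IGHA and IGHG cells of the skull (upper row) and sternum (lower row) libraries. Skull IGHA cells had a median of 1225 UMIs, whereas sternum IGHA cells had a median of 2 and a small group above 100.

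IGHM cells were more frequent in the skull and IGHD cells in the sternum. IGHM was carried by 78.4% of skull cells (1733 of 2210 with a constant gene called, 76.6 to 80.1%) and 61.4% of sternum cells (1291 of 2103, 59.3 to 63.5%). IGHD, the transcript that mature B cells make beside IGHM, was carried by 12.3% of skull cells (10.9 to 13.7%) and 28.4% of sternum cells (26.5 to 30.4%). Class-switched cells were 9.32% (8.14 to 10.6%) and 10.2% (8.96 to 11.6%). IGHA, the mucosal isotype, was carried by 121 skull cells (5.48%, 4.56 to 6.51%) and 197 sternum cells (9.37%, 8.16 to 10.7%). The IGHG genes together accounted for 85 skull cells (3.85%, 3.08 to 4.73%) and 18 sternum cells (0.856%, 0.508 to 1.35%). Of these, IGHG1 had 38 and 4 cells, IGHG2B 21 and 11, IGHG2C 24 and 1, and IGHG3 2 and 2. No IGHE cell was found among 2210 and 2103 cells, which allows shares of up to 0.136% and 0.143%.

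The order of the bones in IGHA and in class switching depended on whether cells or clones were counted, and that in IGHG on the UMI minimum. With a minimum of 10 UMIs, chosen after seeing the data, IGHM made up 74.7% of skull and 71.3% of sternum cells. IGHD made up 1.52% and 2.81%. IGHD cells had at most 16 UMIs in the skull and 11 in the sternum, so this minimum kept only 9 and 5 of them. The smaller differences there thus follow largely from the cut. Over clones, IGHA made up 5.54% in the skull (108 of 1948, 4.57 to 6.66%) and 2.35% in the sternum (42 of 1791, 1.70 to 3.16%), and switched clones 8.01% and 3.29%. With a minimum of 3 IGH UMIs, IGHA also lay higher in the skull, at 6.03% against 5.29%. IGHG made up 2.46% and 0.949% of clones, but 6.75% and 8.43% of cells with 10 or more UMIs, and 17 of the 24 skull IGHG2C cells were 1 rearrangement with at most 3 UMIs. Most sternum IGHA cells had few UMIs: 166 of 197 lay under 10 UMIs, and 157 of those 166 belonged to clones of 5 or more cells. In the high-UMI range the IGHM shares were closer between the bones than over all cells, and the order of the IGHG shares turned. IGHM made up 61.8% of skull (56.5 to 66.8%) and 55.9% of sternum high-UMI cells (45.7 to 65.7%), IGHA 27.4% (22.9 to 32.3%) and 30.4% (21.7 to 40.3%), and IGHG 10.8% (7.80 to 14.5%) and 13.7% (7.71 to 22.0%). Each of these intervals overlapped between the bones. Class-switched cells were 138 of 361 skull and 45 of 102 sternum high-UMI cells, further apart than over all cells. The constant genes lie on chromosome 12, from IGHA at 113254830 to 113260236 to IGHM at 113418558 to 113422730.

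**Figure D2:**
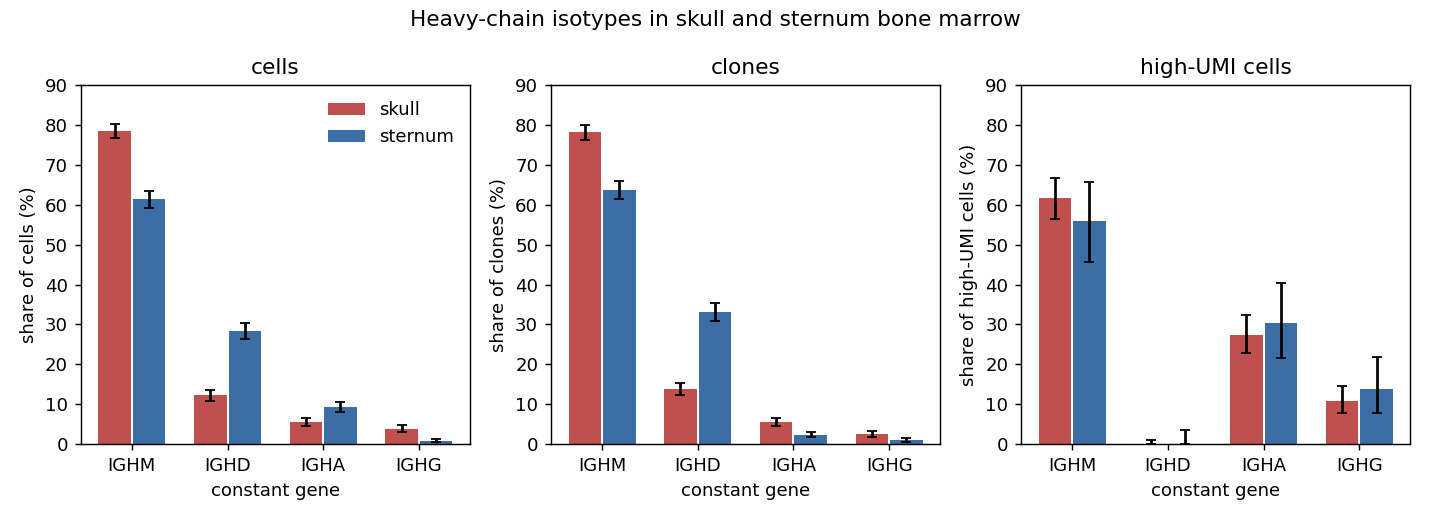
Share of cells, of clones and of high-UMI cells (y axes, %) with each constant gene (x axes) in the skull and sternum libraries; bars are shares and lines are exact 95% intervals of counting error. IGHD was higher in the sternum over cells and clones, IGHA was higher in the sternum over cells and higher in the skull over clones, and the high-UMI shares had overlapping intervals.

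The balance of kappa and lambda chains was alike in the bones. Lambda chains were used by 9.80% of skull cells (177 of 1807, 8.46 to 11.3%) and 9.06% of sternum cells (155 of 1711, 7.74 to 10.5%), a difference that was not detectable at this depth. IGKC, on chromosome 6 from 70726435 to 70726966, was called in 89.8% and 90.7%. Within lambda, IGLC1 was called in 4.93% and 5.90% of cells, IGLC2 in 3.65% (2.84 to 4.62%) and 2.34% (1.68 to 3.17%), and IGLC3 in 1.16% and 0.818%. A second productive light chain was present in 13.5% of skull cells with a light chain (281 of 2088) and 15.8% of sternum cells (320 of 2031).

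IGHV use was broadly shared between the bones. Of the 45 IGHV genes with 30 or more clones, 35 had shares within 1.5-fold of each other. The distal families IGHV1 and IGHV8, which lie far from the D segments, supplied 65.5% of skull clones (63.4 to 67.6%) and 66.9% of sternum clones (64.7 to 69.1%). The proximal families IGHV5 and IGHV2 supplied 12.9% (11.5 to 14.5%) and 11.7% (10.3 to 13.3%). The 5 most used genes were IGHV1-26 (4.62% of skull and 6.19% of sternum clones), IGHV8-8 (4.87% and 3.98%), IGHV9-3 (4.47% and 3.21%), IGHV1-81 (3.73% and 3.87%) and IGHV1-64 (3.28% and 3.04%). All of these genes lie on the minus strand of chromosome 12.

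Among single IGHV genes with 30 or more clones, the skull share was highest relative to the sternum for IGHV5-6 (chromosome 12, 113625506 to 113625956), at 1.54% of skull clones (1.05 to 2.18%) and 0.774% of sternum clones (0.424 to 1.30%). Next came IGHV1-52 (1.73-fold), IGHV1-69 (1.62-fold), IGHV13-2 (1.55-fold), IGHV1-53 (1.52-fold), IGHV1-55 (1.46-fold), IGHV9-3 (1.39-fold) and IGHV1-85 (1.38-fold). The sternum share was highest relative to the skull for IGHV1-76 (chromosome 12, 115847881 to 115848331), at 2.54% of sternum clones (46 clones, 1.87 to 3.38%) and 1.24% of skull clones (25 clones, 0.805 to 1.83%). It was followed by IGHV1-39 at 1.79-fold, IGHV14-4 at 1.77-fold, IGHV2-9-1 at 1.76-fold, IGHV5-9-1 at 1.71-fold, IGHV1-54 at 1.48-fold, and IGHV1-82 and IGHV1-19 at 1.47-fold. Of these 16 genes, only IGHV1-76 had intervals that did not overlap between the bones. The 16 were picked by their ratios from the 45 ranked genes, and the intervals do not allow for that choice. The interval of the difference in percentage points excluded 0 for IGHV1-76 (-2.22 to -0.44), IGHV5-6 (0.08 to 1.48), IGHV9-3 (0.04 to 2.49) and, narrowly, IGHV1-39 (-1.47 to -0.00). Outside these 16, that of the most used gene, IGHV1-26, did so too (-3.04 to -0.14). Among clones with 10 or more IGH UMIs, a minimum chosen after seeing the data, IGHV1-76 was used by 7 of 533 skull clones (1.31%) and 2 of 160 sternum clones (1.25%). Counted over cells, IGHV1-53 was higher in the sternum, at 3.34% against 1.79%, with 49 of its 71 sternum cells in 1 rearrangement.

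**Figure D3:**
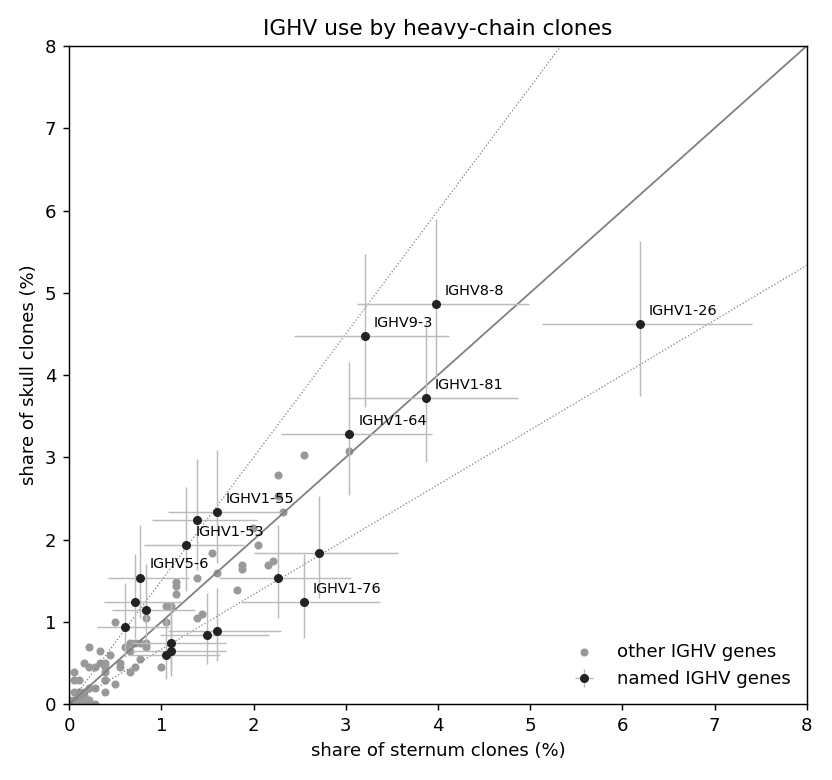
Share of skull clones (y axis, %) against share of sternum clones (x axis, %) for each IGHV gene, with exact 95% intervals for the named genes; the solid line marks equal shares and the dotted lines 1.5-fold. Most genes lie near equal shares, and IGHV1-76 (1.24% of skull and 2.54% of sternum clones) has the lowest ratio of skull to sternum shares among genes with 30 or more clones.

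The B-1 gene list was found in both bones at like shares of clones. IGHV11-2 and IGHV12-3, used by B-1 cells that bind phosphatidylcholine, together with IGHV11-1 made up 1.44% of skull clones (29 of 2013, 0.967 to 2.06%) and 1.27% of sternum clones (23 of 1809, 0.808 to 1.90%). IGHV11-2 was used by 15 and 12 clones and IGHV12-3 by 14 and 11, while IGHV11-1 was not seen, which allows up to 0.149% and 0.166%. Over cells the list reached 4.15% in the skull and 3.15% in the sternum. IGHV11-2 was paired with its usual partner IGKV14-126 in 10 of 12 skull and 7 of 11 sternum clones with 1 light chain, and IGHV12-3 with IGKV4-91 in 3 of 11 and 6 of 9. Over all clones IGKV14-126 was used by 2.17% (1.5 to 3.01%) and 1.73% (1.13 to 2.55%), and IGKV4-91 by 0.510% and 0.555%. In the high-UMI range IGHV11-2 made up 8 of 311 skull clones (2.57%, 1.12 to 5.01%) and 4 of 92 sternum clones (4.35%, 1.20 to 10.8%). IGHV7-1 was used by 12 skull and 8 sternum clones, and its partner IGKV7-33 by 0 of 1570 and 0 of 1441 clones, which allows up to 0.191% and 0.208%. IGHV5-2, the V gene close to the D segments that early B cells favour, was used by 6 and 2 clones, and IGHV1-72 by 61 (3.03%, 2.33 to 3.88%) and 46 (2.54%, 1.87 to 3.38%).

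Among V genes with 30 or more clones, light-chain genes reached larger ratios than IGHV genes. IGKV3-2 (chromosome 6, 70698449 to 70699067) was used by 3.82% of skull clones (60 of 1570, 2.93 to 4.89%) and 1.46% of sternum clones (21 of 1441, 0.904 to 2.22%). IGKV12-46 was used by 4.46% (3.49 to 5.60%) and 1.87% (1.24 to 2.71%). IGKV4-55, IGKV19-93 and IGLV2 were higher in the skull by 1.64-fold, 1.48-fold and 1.42-fold. In the other direction, IGKV3-5 was used by 0.955% of skull clones (0.536 to 1.57%) and 2.85% of sternum clones (2.05 to 3.84%), and IGKV3-4 by 1.15% (0.681 to 1.81%) and 2.64% (1.87 to 3.60%). IGKV17-121, IGKV6-23 and IGKV13-84 were higher in the sternum by 1.95-fold, 1.83-fold and 1.51-fold, though with 3 or more IGH UMIs IGKV13-84 was at 0.98% in the skull and 0.92% in the sternum. Below that number of clones, IGKV5-45, named after its values were seen, was used by 19 skull clones (1.21%, 0.730 to 1.88%) and 0 of 1441 sternum clones, which allows up to 0.208%. In the high-UMI range of the skull 2 clones used it, both with IGHV1-78. Whether its clones repeated 1 light rearrangement, or kept this difference at a minimum of light UMIs, was not examined. The 3 most used genes were IGLV1 (6.50% and 7.01%), IGKV10-96 (3.57% and 5.20%) and IGKV1-135 (2.99% and 4.02%).

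For IGKV3-5 in the sternum, IGKV3-2 in the skull and IGLV2 in both bones, most clones had the same light rearrangement. The most frequent IGKV3-5 rearrangement accounted for 24 of the 41 sternum clones, with a median of 3 UMIs, and that of IGKV3-2 for 33 of the 60 skull clones, with up to 13087 UMIs in 1 cell. That of IGLV2 accounted for 36 of 45 skull and 18 of 29 sternum clones. Among light contigs with 10 or more UMIs, a minimum chosen after seeing the data, the IGKV3-5 difference narrowed to 1.10% against 1.71%, and IGKV10-96 became 3.81% in the skull and 3.60% in the sternum. IGKV3-2 (3.67% and 1.89%), IGKV12-46 (3.45% and 2.07%) and IGKV3-4 (1.25% and 2.43%) kept their order there, and without its most frequent rearrangement in each bone IGKV3-2 still had 27 skull and 14 sternum clones.

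J and D segments were used at similar shares. Over clones, IGKJ2 was the only J segment whose difference had an interval that excluded 0. IGHJ1, IGHJ2, IGHJ3 and IGHJ4 made up 18.5%, 29.8%, 25.9% and 25.8% of skull clones and 18%, 30.8%, 24.8% and 26.4% of sternum clones. Of the kappa segments, IGKJ2 differed most, at 28.0% of skull kappa clones (25.7 to 30.4%) and 32.0% of sternum kappa clones (29.5 to 34.6%). These share intervals overlapped, and the difference was -4.01 percentage points (-7.46 to -0.55). Over cells the differences of IGKJ2 (-3.83, -7.04 to -0.62), IGHJ2 (-3.28, -6.02 to -0.54) and IGKJ5 (3.13, 0.20 to 6.05) had intervals that excluded 0. IGKJ1 was used by 33.0% and 31.1%, IGKJ4 by 14% and 13.9%, and IGKJ5 by 25.1% and 23.1%. A D segment was called in 20.9% of skull and 18% of sternum clones, and shares of single segments refer to those. IGHD1-1, a long D segment, was called in 37.6% (33.0 to 42.4%) and 39.1% (33.7 to 44.6%), and the short IGHD4-1 in 11.9% and 10.8%. Heavy CDR3 had a mean length of 13.95 ± 2.88 amino acids (SD over 2013 clones) in the skull and 14.01 ± 2.73 (SD over 1809 clones) in the sternum. Its mean net charge was -0.20 and -0.22. Class-switched clones had mean lengths of 13.48 and 13.64, and unswitched clones of 13.97 and 14.02. Clones with IGHD4-1 averaged 11.78 and 12 amino acids and those with IGHD1-1 17.18 and 17.12.

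The share of cells in expanded clones was similar over all cells, and its differences by isotype depended on the UMI range. Expanded clones held 15.3% of skull cells (350 of 2289, 13.8 to 16.8%) and 17.1% of sternum cells (364 of 2125, 15.6 to 18.8%). These levels depended on the rule, with 8.34% and 9.04% by the authors' clonotype numbers, 9.21% and 8.96% with a minimum of 3 UMIs, and 20.75% in each bone at 85% CDR3 identity. Over all barcodes with an IGH contig they were 15.2% and 17.6%, a difference of -2.37 points whose interval excluded 0 (-4.50 to -0.25). Among IGHM and IGHD cells the shares were 13.4% (12 to 15%) and 10.3% (8.99 to 11.8%). Among class-switched cells they were 31.6% (25.3 to 38.4%) and 76.7% (70.5 to 82.2%), and among IGHA cells 17.4% (11.1 to 25.3%) and 82.7% (76.7 to 87.7%). Most sternum IGHA cells came from a few rearrangements whose cells are not independent, so the sternum intervals here are too narrow. IGHG cells went the other way, with 51.8% (44 of 85, 40.7 to 62.7%) and 11.1% (2 of 18, 1.38 to 34.7%). The order of the bones turned for class-switched, IGHA and IGHG cells when high-UMI cells alone were counted, as given below for IGHA and IGHG (class-switched 6.52% and 4.44%). At 2125 cells per library the inverse Simpson index was 842 in the skull and 401 in the sternum, and the Shannon effective number of clones 1582 and 1319. These values depend on the largest clones. The 5 largest of the sternum (49, 48, 45, 29 and 23 cells) had medians of 2 UMIs or fewer. Diversity was not computed without low-UMI cells.

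The largest clones were mostly sets of low-UMI cells with many different light chains. In the sternum, IGHV1-53 with IGHJ2 was found in 49 IGHA cells with at most 4 UMIs, and the 45 of them with 1 light chain carried 17 different light rearrangements. The sternum clones that followed were IGHV1-26 with IGHJ1 (48 IGHM cells, 25 light rearrangements in 45 cells), IGHV1-76 with IGHJ2 (45 IGHA cells, at most 7 UMIs), IGHV11-2 with IGHJ1 (29 cells, 28 of them IGHM) and IGHV1-5 with IGHJ3 (23 IGHA cells, median 2 UMIs and 1 cell at 2686). In the skull they were IGHV11-2 with IGHJ1 (40 cells, 34 of them IGHM), IGHV1-9 with IGHJ4 (20 cells, 13 light rearrangements in 14 cells), IGHV1-5 with IGHJ2 (19 IGHM cells), IGHV1-69 with IGHJ2 (17 IGHG2C cells, at most 3 UMIs) and a further IGHV11-2 with IGHJ1 (12 IGHM cells, median 210.5 UMIs).

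Among high-UMI cells alone, most cells in expanded clones were IGHM. Expanded clones held 22.7% of skull high-UMI cells (82 of 361, 18.5 to 27.4%) and 16.7% of those of the sternum (17 of 102, 10.0 to 25.3%). For IGHM the shares were 32.7% (73 of 223, 26.6 to 39.3%) and 26.3% (15 of 57, 15.5 to 39.7%). For IGHA they were 6.06% (6 of 99, 2.26 to 12.7%) and 0 of 31 cells, which allows up to 9.68%, and for IGHG 7.69% (3 of 39, 1.62 to 20.9%) and 14.3% (2 of 14, 1.78 to 42.8%). The largest skull clone of this range was IGHV6-3 with IGHJ1, with 7 IGHM cells that all carried the same IGKV3-2 rearrangement. In the sternum it was IGHV11-2 with IGHJ1, with 5 IGHM cells. This restriction was chosen after seeing the data.

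**Figure D4:**
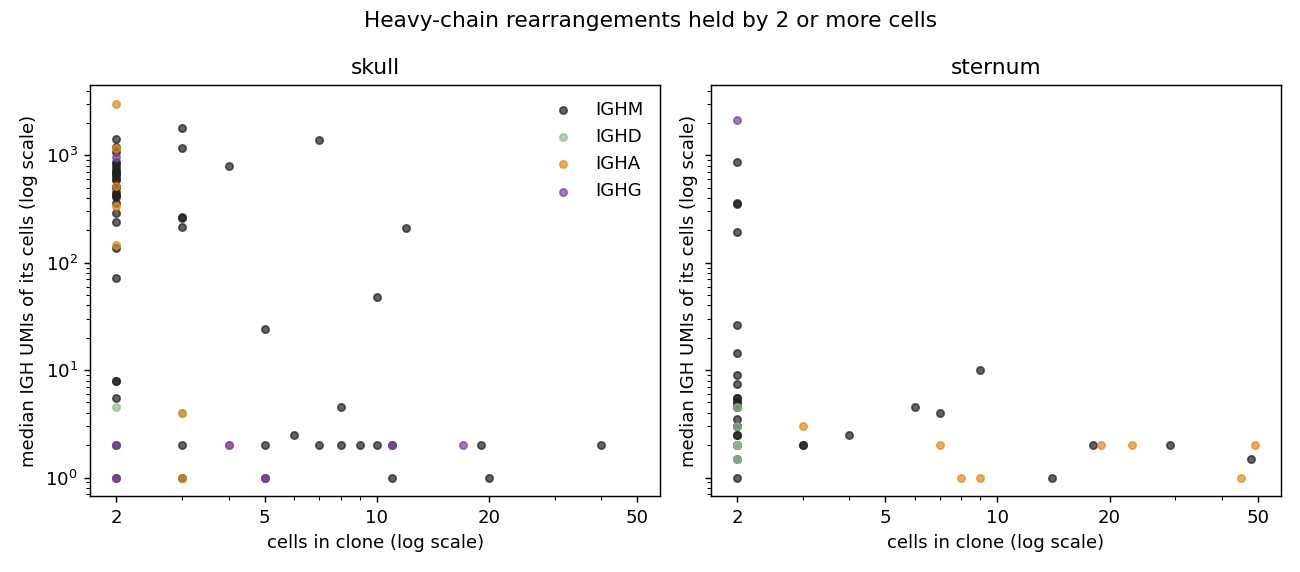
Each point is a heavy-chain rearrangement found in 2 or more cells of the skull or sternum library, by the number of its cells (x axis, log scale) and their median IGH UMIs (y axis, log scale), coloured by its most frequent isotype. Clones of 20 or more cells lie at a median of 2 UMIs or fewer, and those with medians above 100 have at most 12 cells.

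The libraries shared 22 heavy-chain clones. Of these, 6 used the B-1 genes IGHV11-2 or IGHV12-3, and 15 reached the high-UMI range in both bones. The isotype was IGHM in both bones for 19 of them and IGHA in both for 2. By total cells the first 10 were IGHV1-26 (3 skull and 48 sternum cells), 3 clones of IGHV11-2 (12 and 29, 10 and 9, 5 and 6), IGHV6-3 (7 and 2), IGHV1-53 (3 and 1, IGHA), IGHV1-75 (1 and 3, IGHA), IGHV8-8 (3 and 1), IGHV1-36 (2 and 1) and IGHV1-50 (2 and 1). All but IGHV1-53 and IGHV1-75 were IGHM. The most abundant cells of the clone had the same light rearrangement in both bones for 12 of the 22, and for 10 of the 16 outside the B-1 genes. The 15 clones that were high-UMI in both bones made up 16.3% of the 92 high-UMI clones of the sternum and 4.82% of the 311 of the skull. Counted as combinations of heavy and light rearrangement, 18 were shared, from 15 of the 22 clones, and 29 clones were shared when the CDR3 was compared as amino acids.

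Mutation of IGHV was more frequent in the skull over all clones, where high-UMI clones were a larger part. Clones with 2 or more mismatches were 8.92% of skull clones (178 of 1996, 7.70 to 10.3%) and 3.64% of sternum clones (65 of 1787, 2.82 to 4.61%). With a minimum of 10 UMIs, chosen after seeing the data, the order turned, at 29.1% and 31.4%. Among unswitched clones the shares were 5.11% (4.14 to 6.24%) and 1.69% (1.14 to 2.42%), and among unswitched clones below the high-UMI range 1.37% (0.861 to 2.07%) and 0.781% (0.417 to 1.33%). High-UMI IGHM clones were mutated in 39.2% (69 of 176, 31.9 to 46.8%) and 33.3% (16 of 48, 20.4 to 48.4%). Class-switched clones were mutated in 54.2% (83 of 153, 46.0 to 62.3%) and 63.2% (36 of 57, 49.3 to 75.6%). IGHA clones had a mean of 3.61 ± 3.91 mismatches (SD over 106 clones) in the skull and 3.75 ± 3.24 (SD over 40 clones) in the sternum, and IGHG clones 2.15 ± 2.73 (SD over 47 clones) and 2.71 ± 3.10 (SD over 17 clones).

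**Figure D5:**
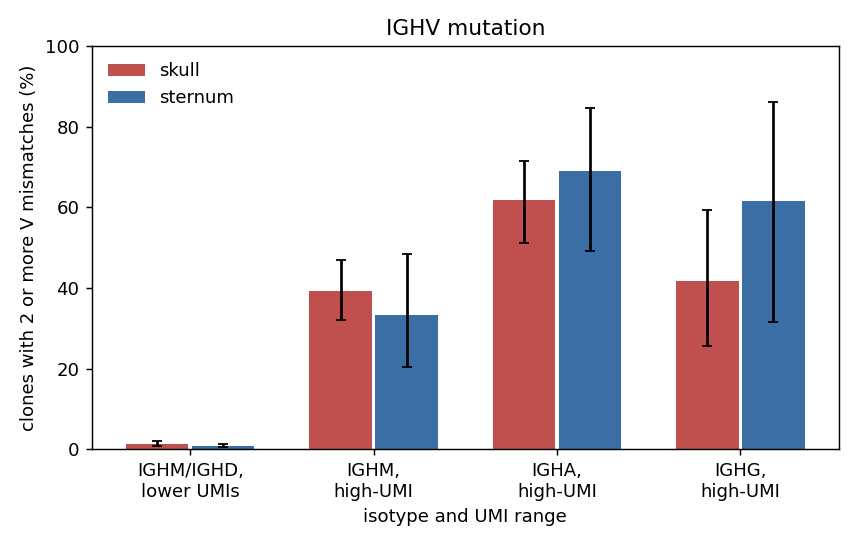
Share of clones with 2 or more IGHV mismatches (y axis, %) for unswitched clones below the high-UMI range and for high-UMI IGHM, IGHA and IGHG clones (x axis) in the skull and sternum libraries, with exact 95% intervals. Mutated clones were rare below the range (1.37% and 0.781%) and frequent in each high-UMI isotype of both bones, with overlapping intervals.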

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

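The tests on barcodes with 2 heavy chains, on light chains within rearrangements, without repeated rearrangements, on barcodes in common and on matching light chains were chosen after the results were seen, or after the counts they rest on had been seen in part, as was the comparison of reads per UMI across the libraries; those at equal UMIs, on reads per UMI within each library and on common mismatches were fixed before.

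Expansion by isotype went in opposite directions in the bones, a difference that was not tested: the share of cells in expanded clones, IGHA minus IGHG, was -34.4 percentage points in the skull and 71.6 in the sternum. Among high-UMI cells only, a restriction chosen after seeing the data, it was negative in both, at -1.63 and -14.3 points. Of cells under 10 UMIs, 157 of 166 sternum IGHA cells and 32 of 45 skull IGHG cells belonged to clones of 5 or more cells; the skull IGHG cells were not tested further. The sternum IGHA cells with few UMIs were held mainly by 7 rearrangements of 5 or more cells. Of their low-UMI members with 1 light chain, 46.3% (63 of 136, 37.7 to 55.1%) carried the most frequent light chain of the rearrangement. In multi-cell high-UMI clones 90.3% did (84 of 93, 82.4 to 95.5%). Those clones had at most 7 cells in the skull and 5 in the sternum, against up to 49 here, and a small clone raises this share. They also had more UMIs, so the comparison cannot decide on division of IGHA B cells, which stays open. Free RNA of a few antibody-secreting cells remains a candidate explanation, and it predicts these rearrangements in barcodes that already have a heavy chain. They were present in 20.9% of sternum barcodes with 2 heavy chains (24 of 115, 13.8 to 29.4%) and 7.53% of those with 1, a rise whose interval still includes the doubling that doublets would give. Of the 7 rearrangements, IGHV1-5 (23 cells), IGHV1-22 (19) and an IGHV7-3 (9) reached 2686, 445 and 2043 UMIs in a cell. The others, among them the largest of 49 and 45 cells, had at most 7 UMIs in any cell. For those, no source cell of free RNA was seen in the main population.

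IGHD was carried by more sternum than skull cells, a skull minus sternum difference of -18.1 percentage points among IGHM and IGHD cells. Free IGHM RNA in the skull library stays open. The difference was -19.3 points among cells whose rearrangement was held by 1 barcode. That restriction removed only 269 of 2004 skull and 195 of 1888 sternum IGHM and IGHD cells. These were too few to shrink the difference much, so the test could not decide. Fewer IGH UMIs per cell in the sternum stay open as a cause of a part, as the difference was -11.7 points at equal UMIs, with the intervals apart in 3 of 8 UMI strata. Reads per UMI stay open too, and were compared only in IGHM and IGHD cells with 2 to 9 IGH UMIs. Within the skull library the IGHD share of these cells was 16.9 points higher above the median of reads per UMI than below, and within the sternum 31.5 points. Yet the lower sternum range had more reads per UMI than the upper skull range (medians 126 and 51.5) and a lower IGHD share (17.6% and 25.5%). IGHD contigs that draw more reads would give the same values within a library, and a different share of mature B cells in the marrows is also open and untested.

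The 22 clones found in both libraries were weighed against carry-over of reads and chance. Reads carried over between libraries are argued against, as 0 of the 22 shared rearrangements had a barcode in common. This covers reads exchanged after barcoding and cannot address material mixed before it, which would take other barcodes. Of the 34 barcodes found in both libraries, 1 had the same contig in both, an IGLV1 light rearrangement that occurred in 24 skull and 70 sternum contigs. Independent recombination without selection is argued against for those outside the B-1 genes that reached the high-UMI range in both bones, of which 69.2% had the same light rearrangement (9 of 13, 38.6 to 90.9%), against 0.34% of unrelated pairs. For one mutated lineage present in both bones the test was open, with 0 shared rearrangements having 2 or more uncommon mismatches in common and 4 having at least 1, among 9 with mismatches in both. Recurrent selection of the same receptor and 1 lineage in both marrows cannot be told apart, since the labels do not say whether the libraries share animals.

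Barcodes outside the main population also held strong signals. Light chains with 100 or more UMIs were found in 17 skull and 9 sternum barcodes that had no heavy chain. Both heavy chains reached 50 or more UMIs in 18 of the 149 skull barcodes with 2 heavy chains, and in 0 of the 115 in the sternum, which allows up to 2.61%.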

How the results depend on the processing

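The minimum of 10 UMIs for heavy or light contigs, the restriction to high-UMI cells and the skull limit in both libraries were chosen after seeing the data; other alternatives were fixed before. Values are skull minus sternum in percentage points. Over 15 comparisons, 64 of 89 alternative values stayed within the 95% interval of the reported difference or, for counts, within 1.5 times; 21 moved and 4 reversed. Reversed means a change of sign from a difference whose interval excluded 0; 7 of the 21 that moved changed sign from one whose interval included 0. The causes were not tested unless stated. Lambda use (0.04 to 0.74), distal IGHV families (-3.14 to -0.15), the mutated share of class-switched clones (-17.36 to -7.05) and the shared clone count (15 to 29 against 22) stayed so under every alternative run. For lambda, cells with 1 IGH and 1 light chain are the reported population itself, so that value could not differ. Over cells, the intervals of the distal families (-5.91 to -0.35) and the switched mutated share (-26.39 to -7.91) excluded 0. The reported ones included it (-4.36 to 1.64 and -22.71 to 6.18).

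With clones as the unit, the class-switched difference went from -0.90 to 4.71, IGHA reversed from -3.89 to 3.20, IGHD went from -16.13 to -19.25 and IGHG from 2.99 to 1.51. With a minimum of 3 UMIs the same differences were 2.16, 0.73 (reversed), -12.66 and 1.42. With a minimum of 10 UMIs, IGHA was -0.38, IGHD -1.29, IGHG -1.68 (reversed), proximal IGHV genes -0.93 (reported 1.20), the B-1 list -1.12 (reported 0.17), cells in expanded clones 1.58 (reported -1.84), mean CDR3 length 0.43 amino acids (reported -0.06) and all mutated clones -2.27 (reported 5.28, reversed). The IGHD value at 10 UMIs rests on 9 skull and 5 sternum IGHD cells. Among high-UMI cells only, cells in expanded clones differed by 6.05. The shares of class-switched and IGHA cells in expanded clones reversed from -45.19 and -65.39 to 3.45 and 7.92 with 10 UMIs and to 2.08 and 6.06 in high-UMI cells. Over cells, the B-1 list differed by 1.0, all mutated clones by 2.27 and unswitched mutated clones by 5.13 (reported 3.42). A limit of 1 mismatch gave 7.69 for all and 5.64 for unswitched clones, and 4 mismatches 3.28 and 2.0, as a change of the limit itself must move them. The high-UMI share differed by 13.25 in cells with 1 IGH and 1 light chain (reported 10.97) and by 10.36 to 11.21 under its other alternatives. Of 185 alternative values for the 33 named V genes, 172 stayed within the interval, 11 moved, 2 of them with a change of sign (IGHV1-53 to -1.55 over cells and IGHV1-82 to 0.88 with 10 UMIs), and 2 reversed: IGHV1-76 to 0.06 with 10 UMIs and IGKV10-96 to 0.21 with light contigs of 10 or more UMIs.

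No paired analysis was possible because each bone had 1 library. The sternum library's 102 high-UMI cells and 18 IGHG cells limit what its shares of isotypes can show.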

Other observations

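The pairs and clones here were chosen after their values were seen. High-UMI clones of both bones repeated certain heavy and light V pairs. IGHV1-50 was paired with IGKV4-70 in 7 of 9 skull and 5 of 6 sternum high-UMI clones, where independent pairing of the V genes would give 0.20 and 0.33 clones. All 12 of these clones were IGHM, and their CDR3 lengths ran from 9 to 12 amino acids. Below the high-UMI range the same pair was found in 2 of 23 skull and 0 of 33 sternum IGHV1-50 clones with a light chain. IGHV1-50 supplied 4 of the 22 clones shared by the bones, each with IGKV4-70 and each in the high-UMI range in both. IGHV1-50 lies on chromosome 12 from 115119748 to 115120219 and IGKV4-70 on chromosome 6 from 69267888 to 69268443.

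Other repeated pairs of high-UMI clones were IGHV6-3 with IGKV3-2 (9 skull and 2 sternum clones, 0.62 and 0.17 by independent pairing), IGHV11-2 with IGKV14-126 (6 and 4 clones, 0.15 and 0.17), IGHV8-8 with IGKV4-68 (5 and 2 clones, 0.50 and 0.13) and IGHV1-80 with IGKV4-55 (5 and 2 clones, 0.35 and 0.16). IGHV8-5 was paired with IGLV1 in 6 of 6 skull clones of this range. Clones here differ by at least 1 CDR3 nucleotide, so related members of 1 mutated lineage count separately. In the skull, 3 expanded IGHV6-3 rearrangements with different nucleotides, of 11, 7 and 3 cells, encoded the same CDR3, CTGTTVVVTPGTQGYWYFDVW, which a sternum rearrangement of 2 cells encoded as well.

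Antibody genes of high-UMI IGHM clones carried mismatches in both bones, with means of 1.70 ± 2.26 (SD over 176 clones) in the skull and 1.46 ± 2.36 (SD over 48 clones) in the sternum, and 77 and 26 of these clones had none.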
